A study of Mus musculus with 9 samples.

How the data were processed

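The series holds 9 bulk RNA libraries of sorted mouse thymic tuft cells, 5 from untreated mice and 4 from mice irradiated with 425 rad 3 days before the thymus was taken. Per the labels, tissue was digested with Liberase TH plus DNase before tuft cells were sorted, and libraries were made from polyadenylated RNA by MARS-seq, which reads the 3' end of transcripts. The gate used in the sort, the number of cells and whether each library came from a separate mouse are not given in the sources used here. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2 and the genome build mm10, without saying what each was used for. Whether unique molecular identifiers were collapsed and which strand setting was used are not given in the sources used here, so a count below may be a read or a molecule.

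A single table was deposited, with 13223 gene symbols. Per the file headers, its raw columns hold counts per gene, which the values bore out as whole numbers. Each listed gene reached at least 6 counts in some library, so the deposited table had been filtered by the authors before it was released. The deposited normalized columns hold the signal per gene as counts divided by a single size factor per library, checked against the raw columns, and the mean over libraries was deposited beside them. The deposited regularized columns hold log2 values, per the file headers from the regularized logarithm of DESeq2, and were not used. The authors' comparison holds a log2 fold change of untreated over irradiated, whose sign was checked against the counts, and whether it was shrunken is not stated. The deposited p-value columns belong to that comparison, and the adjusted column equalled the Benjamini-Hochberg adjustment over the table. Other deposited columns give the authors' flag for passing and the direction of change, and the passing genes had an absolute log2 fold change of at least 1, a mean of at least 5.31 and an adjusted p of at most 0.0488 in the authors' table. No column belonged to a sample outside the series.

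Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 8934, libraries were scaled by TMM, and groups were compared with robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over all tested genes at 0.05. The standard error of a fold change is its size divided by the square root of F. The biological coefficient of variation was 28.9%. Among tested genes 946 had an unadjusted p under 0.05, against 446.7 that chance alone would give, and the median log2 fold change of all tested genes was -0.02. The groups did not overlap for 5.14% of tested genes, against 1.59% by chance. Principal components were taken from log2 CPM of the tested genes. Library totals ran from 509157 to 978442 counts, a ratio of 1.92. A gene without counts in a group was only bounded, against a floor of 3 counts over the group. A gene with some counts there, but no more than 3, is given a pooled ratio with an exact interval beside its fitted value. Symbols were placed with the mm10 annotation of GENCODE, which held 13008 of them.

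Gene lists, 34 in all, were tested as sets with camera from limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and at least 5 tested genes per list, adjusted over the 29 lists that qualified. They cover tuft cell identity, taste, eicosanoids, type 2 cytokines, p53 targets, DNA repair, apoptosis, cell cycle, interferon, class I and class II presentation, NF-kB, immediate early genes, thymus growth factors, ribosomal proteins, oxidative phosphorylation, mitochondrial genes, unfolded proteins, cholesterol and glycolysis, and the markers of 14 other cell types. Some genes are in several lists. For each list of other cell types, CPM were summed per library, and log2 of the sum plus 1 was compared by a two-sided exact permutation test over all 126 splits of the libraries. The comparison, tests, lists and naming rule were set before the data were examined. The rule named 15 genes of tuft cells, p53 and cell type identity, and up to 12 rises and 12 falls with the largest fold change among called genes with a mean of at least 20 CPM and groups that did not overlap. It also named up to 4 tested members of each list with the smallest p, or up to 6 where camera called the list. Genes named beyond it are said to have been chosen after their values were seen.

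Alternatives set beforehand were DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter of at least 10 CPM in at least 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, a replicate block, thinning to the smallest library, leaving out the 20 most abundant genes, a log2 fold change of at least 1, camera with an estimated correlation, a pseudocount of 10 for marker totals, and leaving out each library. Those added after the data were seen were replicates 1 to 4 without a block, a permutation test of list means, leaving out untreated replicates 1 and 2, and leaving out untreated replicate 2 with irradiated replicate 4. The methods were tested on simulated data with known changes. There edgeR recovered 27.6% of 98 genes changed 2-fold and 86% of 93 changed 4-fold with 6 false calls among 113, DESeq2 34% and 85% with 12 false among 131, and limma-voom 23.5% and 79.6% with 5 false among 102. With no change simulated edgeR called 0 genes and DESeq2 2, and camera called a raised p53 list and none of the other lists. Simulated genes were drawn independently, so this does not test camera on lists whose genes move together. In the data the estimated correlation was 0.836 for the class II list. All 16 pairs of replicates within groups differed beyond counting error (chi-square per gene of 2.561 to 12.69). The 3 pairs with irradiated replicate 4 had 9.971 to 12.69, and the 4 pairs with untreated replicate 2 had 9.633 to 11.37. Exons of Dclk1, Il17rb, Ltc4s, Lrmp, Ube2c, Irf1, Ppp1r15a and Kif22 overlap those of genes on the opposite strand, and those of Bax, Col3a1, Fdps, Lck, Rtp4 and Top2a overlap genes on the same strand, so their levels are uncertain.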

Results

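Tuft cells are rare chemosensory epithelial cells, which in the thymus lie in the medulla and make the cytokine interleukin 25. Tuft cells were sorted from dissociated thymi of young wild-type female mice that had received a sublethal dose of 425 rad 3 days earlier, and from untreated mice of matched age. Gene expression was measured by bulk MARS-seq, a method that sequences the 3' ends of polyadenylated transcripts from a pool of cells. The series held 5 libraries of untreated mice and 4 of irradiated mice, and its title places the comparison in a study of thymus regeneration and type 2 immunity. The question addressed here is how the transcriptome of sorted tuft cells differed between the groups 3 days after irradiation. The labels call the libraries replicates without tying each to its own mouse, so the p-values measure the spread between these libraries, which may in part be technical. Untreated replicates 1 to 5 held 978442, 696400, 770322, 729178 and 686082 counts, and irradiated replicates 1 to 4 held 667920, 939948, 891470 and 509157. The mean total was 772085 ± 119950 counts (SD, n = 5) in the untreated and 752124 ± 200681 (SD, n = 4) in the irradiated group, so 1 count was worth between 1.04 and 2.10 CPM (counts scaled to a common library total). Between 12634 and 12917 of the 13223 listed genes were detected in untreated libraries and between 11747 and 12691 in irradiated libraries. No gene took more than 1.02% of any library. On the first principal component, with 35% of the variance, irradiated replicate 4 lay at 75.08 and the other 8 libraries between -31.77 and 6.12. Expression levels below are TMM-scaled CPM, given as mean ± SD over the 5 untreated and 4 irradiated libraries, and changes are log2 fold changes of irradiated over untreated ± SE.

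Irradiation was followed by higher expression of 109 genes and lower expression of 11 among the 8934 genes tested. The largest rise among the named genes was that of Upk3b, a uroplakin of epithelial surfaces. It went from 12.6 ± 2.46 to 245 ± 78.0 CPM, a 19.2-fold change. Upk3b, Rspo1, Lrrn4 and Gpm6a, all among the named rises, are also associated with mesothelium. Whether mesothelial RNA was a source is left open below. Gdf15, a stress-induced cytokine of the TGF-beta superfamily and a p53 target, rose 10.9-fold, from 63.0 ± 19.7 to 690 ± 452 CPM. Igfbp6, which binds insulin-like growth factor 2, rose 7.21-fold from 97.0 ± 25.5 to 701 ± 244 CPM, and Fosl1, a subunit of the AP-1 transcription factor, rose 6.90-fold from 12.8 ± 5.09 to 89.1 ± 13.1 CPM. The WNT agonist Rspo1 rose from 8.84 ± 2.62 to 72.8 ± 20.2 CPM and the actin cross-linker Flnc from 2.71 ± 1.58 to 42.4 ± 15.7 CPM.

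The 12 named rises spanned log2 fold changes of 2.79 to 4.26. They were 4.26 ± 0.27 for Upk3b (edgeR adjusted p = 1.47e-06), 3.84 ± 0.46 for Flnc (0.000746), 3.44 ± 0.43 for Gdf15 (0.00258), 3.01 ± 0.30 for Rspo1 (0.000130), 2.85 ± 0.25 for Igfbp6 (8.24e-05) and 2.79 ± 0.27 for Fosl1 (0.000130). The membrane proteins Lrrn4 (3.23 ± 0.34), Pkhd1l1 (3.11 ± 0.32), Nkain4 (3.05 ± 0.32) and Gpm6a (2.79 ± 0.45), complement component C4b (2.93 ± 0.33) and the collagen-binding proteoglycan Fmod (2.81 ± 0.39) made up the rest, with edgeR adjusted p between 0.000145 and 0.00730. As the naming rule required, each of the 12 was higher in all 4 irradiated libraries than in all 5 untreated ones. In the mm10 annotation, Upk3b lies on the plus strand of chromosome 5 (136038496 to 136046487), Gdf15 on the minus strand of chromosome 8 (70629393 to 70632456) and Igfbp6 on the plus strand of chromosome 15 (102144362 to 102149511). All 3 are protein-coding and share no exon with another annotated gene. Reads of C4b and its near-identical copy C4a could have been split, and Fosl1 and Nkain4 overlap exons of a gene on the opposite strand, so their levels are uncertain. Flnc rested on 11 counts in the untreated and 124 in the irradiated libraries. Beside these rises, the summed level of fibroblast and pericyte markers was 4950 ± 1369 CPM in untreated and 8343 ± 1785 CPM in irradiated libraries (two-sided exact permutation test, p = 0.0238, adjusted p = 0.0833). The count of higher genes was 62 without untreated replicate 3, 50 without irradiated replicate 1 and 64 without irradiated replicate 2, and the 12 named rises were called in each of the 9 fits that left out 1 library.

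The genes that fell were led by the chemokine Ccl22 and the chemokine receptor Ccr7, both typical of mature dendritic cells. Ccl22 went from 86.0 ± 61.8 to 0.916 ± 1.08 CPM, on 344 counts in the untreated and 2 in the irradiated libraries. The pooled ratio of untreated over irradiated was 131, with an exact 95% interval of 35.9 to 1080 that covers counting error only. Ccr7 went from 54.1 ± 41.8 to 1.65 ± 2.13 CPM on 226 and 5 counts. The trypsin inhibitor Spink1 fell from 107 ± 81.6 to 3.35 ± 2.46 CPM, the lysozyme Lyz1 from 193 ± 124 to 8.55 ± 4.51 CPM and the hormone Fgf21 from 35.5 ± 22.1 to 4.30 ± 3.47 CPM. Smaller falls were those of the chemokine Ccl6, from 92.8 ± 39.1 to 21.4 ± 7.71 CPM, and of the interferon-inducible genes Epsti1, from 87.2 ± 38.6 to 32.2 ± 4.37 CPM, and Gbp4, from 39.4 ± 12.1 to 15.2 ± 4.19 CPM.

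The fitted log2 fold changes of these 8 genes were -6.67 ± 1.18 for Ccl22 (edgeR adjusted p = 0.0279), -4.90 ± 0.82 for Ccr7 (0.0110), -4.81 ± 0.91 for Spink1 (0.0403), -4.44 ± 0.83 for Lyz1 (0.0420), -2.87 ± 0.60 for Fgf21 (0.0314), -2.08 ± 0.37 for Ccl6 (0.01), -1.45 ± 0.31 for Epsti1 (0.0385) and -1.35 ± 0.31 for Gbp4 (0.0497). The fitted value of Ccl22 depends on the prior count and bounds nothing. Ccl22 lies on the plus strand of chromosome 8 (94745590 to 94751699) and Ccr7 on the minus strand of chromosome 11 (99144196 to 99155077) of mm10, and both are protein-coding. Reads of Lyz1 could have been shared with its close paralog Lyz2, and exons of Gbp4 overlap those of Gbp8 and Gbp9, so both levels are uncertain. The other 3 lower genes lay under the level set for naming and were picked out after their values were seen. They were the mitotic genes Cdca8 (25.6 ± 19.8 to 2.03 ± 1.86 CPM) and Kif22 (18.5 ± 7.27 to 4.78 ± 2.51 CPM) and the immune adaptor Samsn1 (17.5 ± 9.85 to 1.71 ± 0.468 CPM). Summed thymocyte markers were 754 ± 864 CPM in untreated and 148 ± 38.9 CPM in irradiated libraries (exact permutation p = 0.0159, adjusted p = 0.0741), with untreated replicate 1 at 2286 CPM. Summed macrophage and dendritic cell markers were 4585 ± 2949 and 2924 ± 658 CPM (exact permutation p = 0.373, adjusted p = 0.515).

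None of the 11 lower calls held in all 9 fits that left out 1 library, and the count fell to 6 without untreated replicate 3, untreated replicate 4 or irradiated replicate 3 and to 2 without irradiated replicate 1 or 2. All 11 kept their sign. Ccl6 was lost only without irradiated replicate 2 (edgeR adjusted p = 0.0598) and Ccr7 only without irradiated replicates 1 or 4 (adjusted p of up to 0.0818). Spink1 was lost without untreated replicate 5 or any irradiated library (up to 0.173), Fgf21 without untreated replicates 4 or 5 or irradiated replicates 1, 2 or 4 (up to 0.129), and Lyz1 in every fit except those without untreated replicates 1 or 2 (up to 0.184). Epsti1 was kept only without untreated replicates 3 or 5 (up to 0.167), and Gbp4 only without untreated replicate 5 (up to 0.142). Ccl22 was lost without any irradiated library (up to 0.133) and fell under the low-count filter in 4 of the 5 fits without an untreated library. Counts of lower genes differed most between tools, with 11 by edgeR and 100 by DESeq2. The higher genes numbered 109 by edgeR and 184 by DESeq2.

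**Figure D1:**
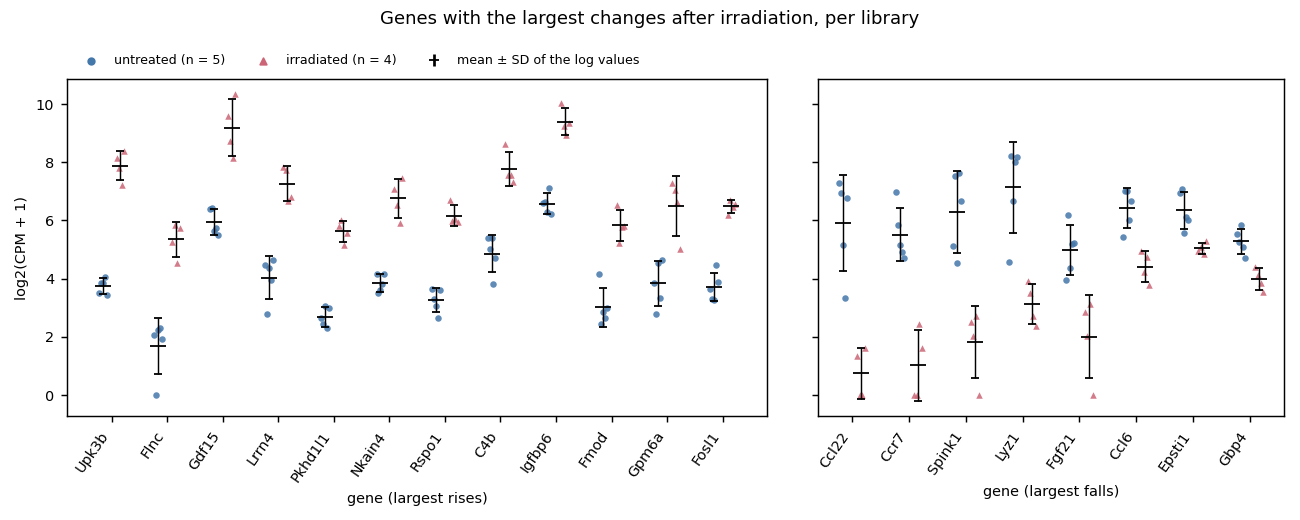
Expression of the 12 named rises (left) and 8 named falls (right), with log2(CPM + 1) on the vertical axis and genes along the horizontal axis. Circles are the 5 untreated and triangles the 4 irradiated libraries, and black bars are the mean ± SD of the log values. The irradiated and untreated libraries do not overlap for any of the 20 genes, which the naming rule required.

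Among the 35 tested targets of the transcription factor p53, the main effector of the DNA damage response, 5 rose, 0 fell and 30 did not pass. The cell cycle inhibitor Cdkn1a rose 2.98-fold, from 357 ± 65.1 to 1064 ± 451 CPM (log2 fold change 1.57 ± 0.25, edgeR adjusted p = 0.00525). The receptor gene Eda2r rose from 4.02 ± 1.28 to 23.1 ± 4.65 CPM (2.47 ± 0.37, edgeR adjusted p = 0.00364). The kinase genes Plk3 (52.99 ± 13.1 to 130 ± 36.6 CPM, edgeR adjusted p = 0.0158) and Plk2 (108 ± 30.6 to 227 ± 61.6 CPM, 0.0389) and Gdf15, above, completed the 5. Mdm2, the ubiquitin ligase of p53, was at 95.4 ± 19.0 and 155 ± 52.99 CPM (edgeR adjusted p = 0.234), and Ccng1 at 75.6 ± 18.5 and 106 ± 43.1 CPM (0.586). Neither passed the test, nor did Phlda3 (61.6 ± 20.4 and 161 ± 75.1 CPM, edgeR adjusted p = 0.0608) or the pro-apoptotic Bax (171 ± 16.8 and 348 ± 177 CPM, 0.0867). Of 21 alternatives, 3 called Mdm2 higher, 1 Ccng1, 5 Phlda3 and 2 Bax. Adjusted over the list alone, 10 targets rose and 1 fell. The list median was 0.36 and the list moved up as a set by camera (adjusted p = 9.66e-07), a call lost with an estimated correlation (adjusted p = 0.1003). Irradiated replicate 4 was the highest library for Cdkn1a (1732 CPM against 744 to 924 in the other irradiated libraries), Gdf15 (1294 against 280 to 768) and Bax (610 against 225 to 295), and the lowest irradiated library for Mdm2 (84.2 against 160 to 212) and Ccng1 (44.2 against 112 to 144). Cdkn1a and Gdf15 were also called without it. Cdkn1a lies on the plus strand of chromosome 17 (29090976 to 29100727) of mm10 and, like Plk3, overlaps exons of a gene on the opposite strand, which without a stated strand setting leaves both levels uncertain. Plk3 was lost without untreated replicate 3 or irradiated replicate 1 (edgeR adjusted p of up to 0.0811), and Plk2 was kept only without untreated replicate 4 or irradiated replicate 2 (up to 0.119).

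Of 26 tested immediate early genes, which respond to stimulation and stress within minutes, 4 rose, 0 fell and 22 did not pass, and 25 had a fold change above 0. Besides Fosl1, these were Fosb (567 ± 187 to 1586 ± 254 CPM, log2 fold change 1.48 ± 0.25, edgeR adjusted p = 0.00764), Jund (421 ± 81.0 to 1063 ± 618 CPM, 1.33 ± 0.30, 0.0455) and the stress gene Ier3 (260 ± 78.1 to 629 ± 293 CPM, 1.27 ± 0.29, 0.0459). Atf3 was at 776 ± 255 and 1630 ± 201 CPM (edgeR adjusted p = 0.0676) and Junb at 1059 ± 283 and 2043 ± 556 CPM (0.0937). With adjustment over the list alone, 18 rose and 0 fell. The median was 0.75 and camera called the list up (adjusted p = 1.95e-14), which was lost with an estimated correlation (adjusted p = 0.199). In irradiated replicate 4 Jund stood at 1989 CPM, against 735 to 784 CPM in the other irradiated libraries. Jund and Junb overlap exons of opposite-strand genes. Jund had a log2 fold change of 0.84 without irradiated replicate 4, and was kept only without irradiated replicates 3 or 4 (edgeR adjusted p of up to 0.120 in the other fits that left out 1 library), and Ier3 only without untreated replicate 4 or irradiated replicate 3 (up to 0.139).

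In the list of the unfolded protein response and chaperones, 1 of 22 tested genes rose and 0 fell. It was Ddit3, a transcription factor of the integrated stress response, from 160 ± 40.7 to 340 ± 61.9 CPM (log2 fold change 1.09 ± 0.21, edgeR adjusted p = 0.0178), and its exons overlap opposite-strand genes. Its partner in that response Ppp1r15a was at 335 ± 75.7 and 639 ± 196 CPM (edgeR adjusted p = 0.0862). Adjusted over the list alone, 2 rose and 0 fell. The median was 0.19, and the camera call (adjusted p = 0.0191) was lost with an estimated correlation (adjusted p = 0.241), without untreated replicate 4 (0.0522) and without irradiated replicate 1 (0.0653, median 0.12). Of 26 tested NF-kB and inflammatory genes, 3 rose and 0 fell, all of them chemokines. Ccl2, which attracts monocytes, rose from 43.4 ± 14.0 to 144 ± 53.6 CPM (1.75 ± 0.29, edgeR adjusted p = 0.00655), Cxcl1 from 305 ± 86.3 to 764 ± 285 CPM (1.32 ± 0.27, 0.0247) and Cxcl2, like Cxcl1 a neutrophil attractant, from 130 ± 47.1 to 288 ± 34.6 CPM (1.15 ± 0.24, 0.0318). Ccl20 was at 260 ± 100 and 65.2 ± 39.6 CPM (edgeR adjusted p = 0.0676). With adjustment over the list alone, 6 rose and 1 fell. The list's median was 0.08 and its mean -0.02, and as a set it did not pass (camera, direction up, adjusted p = 0.0513; adjusted p = 0.562 with an estimated correlation). Camera called it up with upper-quartile scaling (adjusted p = 0.0410), no low-count filter (0.0433), the stricter filter (0.0404) and limma-voom (0.00653), and without untreated replicate 1 (0.0288, median 0.21), untreated replicate 2 (0.00464, median 0.16) or irradiated replicate 4 (0.0373). The median was 0.03 without untreated replicate 5, 0.14 without irradiated replicate 1 and 0.12 without irradiated replicate 2. Cxcl1 was lost without untreated replicates 1, 3 or 5 or irradiated replicates 1 or 2 (edgeR adjusted p of up to 0.0948), Cxcl2 was kept only without untreated replicates 1, 2 or 5 (up to 0.107), and Ddit3 was lost without untreated replicates 3 or 4 or irradiated replicates 1 or 2 (up to 0.0989).

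The genes that define tuft cells differed between the groups by less than the test could call. Of 38 tested tuft cell identity genes, 0 rose and 0 fell, also when adjusted over the list alone, and 25 had a fold change above 0. The cation channel Trpm5 was at 1503 ± 459 CPM in untreated and 1865 ± 372 CPM in irradiated libraries (log2 fold change 0.31 ± 0.25), and the actin-bundling Avil at 2436 ± 739 and 2713 ± 299 CPM (0.16 ± 0.24). The lineage factor Pou2f3 was at 38.5 ± 18.7 and 51.8 ± 13.2 CPM (0.44 ± 0.34), the kinase Dclk1 at 161 ± 40.9 and 140 ± 80.6 CPM (-0.17 ± 0.41), the acetylcholine-synthesising Chat at 35.7 ± 12.5 and 62.2 ± 33.3 CPM (0.76 ± 0.35), and the G protein subunit Gnb3 at 1312 ± 389 and 1509 ± 288 CPM (0.20 ± 0.25). Over the fits that left out 1 library, the fold change ranged from 0.16 to 0.43 for Trpm5, 0.01 to 0.30 for Avil, 0.25 to 0.68 for Pou2f3 and 0.05 to 0.33 for Gnb3, each lowest without untreated replicate 2. Irradiated replicate 4 held 112 CPM of Chat, against 39.0 to 50.4 in the other irradiated libraries, and 29.5 CPM of Dclk1, against 147 to 222, and without it their fold changes were 0.36 and 0.15. Of other members, Espn was at 743 ± 139 and 1145 ± 148 CPM (edgeR adjusted p = 0.191), Lrmp at 2224 ± 619 and 3155 ± 560 CPM (0.483) and Siglecf at 16.3 ± 4.68 and 3.78 ± 3.23 CPM (0.110). Trpm5 and Avil overlap exons of opposite-strand genes. The median of the list was 0.17, and its camera call (adjusted p = 0.0417) was lost with an estimated correlation (adjusted p = 0.758). The call was also lost without untreated replicates 1 or 2 or irradiated replicates 2 or 3 (camera adjusted p of up to 0.662), by limma-voom (0.0802) and without untreated replicate 2 and irradiated replicate 4 (0.104). The median was 0.05 without untreated replicate 2, 0.30 without untreated replicate 5, 0.07 without irradiated replicate 3 and -0.03 without untreated replicates 1 and 2, a setting chosen after the data were seen. Summed tuft cell markers were 21409 ± 6085 CPM in untreated and 25369 ± 3159 CPM in irradiated libraries (exact permutation p = 0.294). Untreated replicates 1 and 2 were lowest, at 17737 and 13318 CPM. The other untreated libraries lay at 22627 to 29140 CPM, much like the irradiated ones at 22437 to 29630 CPM. The epithelial adhesion molecule Epcam was at 259 ± 61.8 and 260 ± 30.2 CPM, with a fold change of 0.01 ± 0.20 that was negative under upper-quartile scaling (-0.03), and the leukocyte phosphatase Ptprc at 52.4 ± 53.7 and 8.07 ± 4.35 CPM (-2.66 ± 0.71, edgeR adjusted p = 0.142; -1.76 without untreated replicate 1).

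Il25, the tuft cell cytokine that drives type 2 responses, was at 223 ± 103 CPM in untreated and 422 ± 21.5 CPM in irradiated libraries. Its log2 fold change of 0.92 ± 0.35 did not pass (edgeR adjusted p = 0.348). The lowest untreated value was 57.8 CPM in replicate 2, and the other 4 untreated libraries lay between 205 and 316 CPM. Il25 lies on the plus strand of chromosome 14 (54932695 to 54935837) of mm10. Its receptor subunit Il17rb was at 176 ± 53.4 and 202 ± 56.5 CPM (edgeR adjusted p = 0.848). Of 12 tested type 2 cytokines and receptors, 1 rose and 1 fell. The alarmin Il33 rose from 22.3 ± 7.81 to 69.6 ± 30.2 CPM (1.63 ± 0.33, edgeR adjusted p = 0.0236), and Ccl22, above, fell. Adjusted over the list alone, 1 rose and 2 fell. The list's median was 0.18 and its mean -0.34, and as a set it did not pass (camera adjusted p = 0.658). The median was 0.06, 0.08 and 0.03 without irradiated replicates 1, 3 and 4 in turn. Il33 was lost without untreated replicates 3, 4 or 5 or irradiated replicates 1 or 2 (edgeR adjusted p of up to 0.131). Of 15 tested genes of eicosanoid synthesis, which makes leukotrienes and prostaglandins, none passed. Alox5 was at 487 ± 194 and 548 ± 72.9 CPM and Ltc4s at 762 ± 165 and 1007 ± 130 CPM (edgeR adjusted p = 0.882 and 0.515). The median of that list was 0.08 and its mean -0.03 (camera adjusted p = 0.506). None of the 14 tested taste and bitter signalling genes passed either, with a median of 0.27 (camera adjusted p = 0.327). That median was 0.10 without untreated replicate 2 and 0.07 without irradiated replicate 3, and camera called the list up without irradiated replicate 4 (adjusted p = 0.0110).

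**Figure D2:**
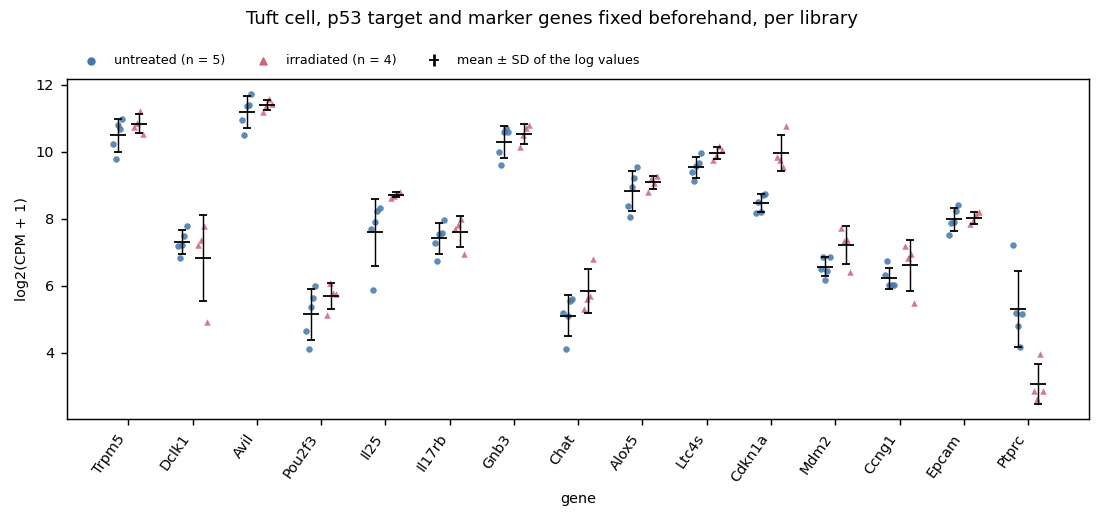
Expression of 15 tuft cell, p53 target and cell type marker genes chosen before the data were examined, with log2(CPM + 1) on the vertical axis and genes along the horizontal axis. Circles are the 5 untreated and triangles the 4 irradiated libraries, black bars are the mean ± SD of the log values, and Cdkn1a is the gene of the 15 that passed the test.

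Few or none of the single genes of proliferation and class II antigen presentation passed. Of 17 tested cell cycle genes, 0 rose, 1 fell and 16 had a fold change below 0. The gene that fell was Cdca8, of the chromosomal passenger complex (log2 fold change -3.40 ± 0.72, edgeR adjusted p = 0.0339), whose exons overlap an opposite-strand gene. Top2a, a topoisomerase of dividing cells, was at 61.6 ± 69.0 and 7.73 ± 2.63 CPM (edgeR adjusted p = 0.186), Ube2c at 53.1 ± 60.1 and 3.25 ± 2.88 CPM (0.122), and Mcm5 at 36.2 ± 30.8 and 7.69 ± 3.53 CPM (0.104). With adjustment over the list alone, 0 rose and 6 fell. The median was -1.08, and the camera call (adjusted p = 5.57e-07) was lost with an estimated correlation (adjusted p = 0.305). Without untreated replicates 1 and 2, a setting chosen after the data were seen, the call was lost as well (camera adjusted p = 0.0524) and the median was -0.43. It was -0.48 without untreated replicate 1, -1.66 without irradiated replicate 4, and -2.41 over all 41 listed members with no low-count filter (camera adjusted p = 1.34e-15). Cdca8 was lost without irradiated replicates 1, 2 or 4 (edgeR adjusted p of up to 0.146) and fell under the low-count filter in 4 of the 5 fits without an untreated library.

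Of 11 tested genes of class II antigen presentation, 0 rose and 0 fell over all genes, while 9 fell when adjusted over the list alone and all 11 fold changes lay below 0. The class II chains H2-Aa (2032 ± 1791 and 484 ± 61.5 CPM, edgeR adjusted p = 0.123), H2-Ab1 (2828 ± 2485 and 789 ± 69.6 CPM, 0.164) and H2-Eb1 (1199 ± 909 and 417 ± 73.9 CPM, 0.219) were the most abundant members named. The median was -1.54, and was -1.01 without untreated replicate 2 and -0.51 without untreated replicates 1 and 2. Camera called the list down (adjusted p = 3.39e-07), which was lost with an estimated correlation (adjusted p = 0.291). The medullary epithelial marker total, which includes H2-Aa itself, was 5771 ± 3985 and 3598 ± 262 CPM and did not pass (exact permutation p = 0.198), with untreated replicate 2 at 12863 CPM. The macrophage and dendritic cell marker list, whose cells also carry class II, had a median of -1.04 with all 18 fold changes below 0 (camera adjusted p = 0.00112, and 0.562 with an estimated correlation). Its median was -0.61 without untreated replicate 1 (camera adjusted p = 0.0681) and -0.14 without untreated replicates 1 and 2 (0.900). The total of those markers, 4585 ± 2949 and 2924 ± 658 CPM, did not pass (exact permutation p = 0.373), with untreated replicate 1 at 9498 CPM.

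Of 38 tested interferon-stimulated genes, 0 rose and 0 fell, and 30 had a fold change below 0. Ifi27l2a was at 1266 ± 144 and 774 ± 110 CPM (log2 fold change -0.71 ± 0.19, edgeR adjusted p = 0.0974) and Rtp4 at 127 ± 21.7 and 75.1 ± 16.5 CPM (0.123), while the transcription factor Irf1 was at 314 ± 50.4 and 485 ± 63.8 CPM (0.146). Adjusted over the list alone, 1 rose and 3 fell. The median was -0.43, and the camera call (adjusted p = 6.74e-06) was lost with an estimated correlation (adjusted p = 0.199). Of 13 tested genes of cholesterol synthesis, 0 rose and 0 fell, and 1 fell when adjusted over the list alone. The farnesyl pyrophosphate synthase gene Fdps was at 66.0 ± 13.2 and 34.8 ± 4.50 CPM (-0.94 ± 0.22, edgeR adjusted p = 0.0580) and Sqle at 48.9 ± 6.48 and 25.9 ± 16.3 CPM (0.403). Of 21 alternatives, 7 called Fdps lower and 0 called Sqle. The median was -0.52, and the camera call (adjusted p = 0.000192) was lost with an estimated correlation (adjusted p = 0.176).

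Markers of other thymic cells were measured to show what else the sorted pools held. Of the 24 thymocyte markers among the deposited genes, the low-count filter kept 8 for testing. The markers left out all had fewer counts over the irradiated than over the untreated libraries, such as Cd8b1 (10 against 220) and Cd3d (9 against 188). Of the 8 tested, 0 rose and 0 fell, and 6 fell when adjusted over the list alone. The T cell surface gene Cd2 was at 22.7 ± 20.3 and 2.39 ± 1.79 CPM (edgeR adjusted p = 0.0669), Tcf7 at 86.2 ± 109 and 5.64 ± 2.38 CPM (0.159) and the kinase gene Lck at 64.7 ± 83.4 and 5.84 ± 2.18 CPM (0.159), with untreated replicate 1 at 214 CPM for Lck. The list median was -3.47, and was -2.28 without untreated replicate 1 and -2.14 without untreated replicates 1 and 2. The camera call down (adjusted p = 3.39e-07) was lost with an estimated correlation (adjusted p = 0.213). All 18 tested macrophage and dendritic cell markers had fold changes below 0, with 0 passing over all genes or over the list alone. Cst3, made by many cell types, was at 1628 ± 851 and 1035 ± 101 CPM (edgeR adjusted p = 0.453) and Mpeg1 at 57.5 ± 72.6 and 6.26 ± 6.66 CPM (0.328). The median of -1.04 was called down by camera (adjusted p = 0.00112), a call lost with an estimated correlation (adjusted p = 0.562) and without untreated replicate 1 (adjusted p = 0.0681, median -0.61). Without untreated replicates 1 and 2 the median was -0.14 (camera adjusted p = 0.900), and without untreated replicate 2 and irradiated replicate 4 the call was lost too (0.0581).

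Of 24 tested fibroblast and pericyte markers, 1 rose and 0 fell, and 7 rose when adjusted over the list alone. The complement inhibitor Serping1 rose from 202 ± 58.4 to 670 ± 115 CPM (log2 fold change 1.72 ± 0.23, edgeR adjusted p = 0.00125). The matrix genes Mgp (553 ± 226 and 1445 ± 596 CPM, edgeR adjusted p = 0.0626), Col3a1 (163 ± 70.0 and 614 ± 349 CPM, 0.107) and Col1a2 (228 ± 125 and 658 ± 202 CPM, 0.146) did not pass. Untreated replicate 2 held 38.5 CPM of Col3a1, against 177 to 200 CPM in the other untreated libraries. The list median was 0.34 and its camera call up (adjusted p = 0.000142) was lost with an estimated correlation (adjusted p = 0.371) and without untreated replicate 2 and irradiated replicate 4 (camera adjusted p = 0.0848, median 0.13), a setting chosen after the data were seen. The median was 0.21 without untreated replicate 2, 0.54 without irradiated replicate 2 and 0.15 without untreated replicates 1 and 2.

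The medulla also holds epithelial cells that express programmes of peripheral tissues, called mimetic cells. Of 10 tested microfold mimetic markers, 1 fell (Ccl6, above) and 0 rose, and 6 fell when adjusted over the list alone. Gp2, a receptor of microfold cells, was at 578 ± 243 and 234 ± 86.8 CPM (edgeR adjusted p = 0.0839). The median was -1.43, and the camera call (adjusted p = 1.13e-05) was lost with an estimated correlation (adjusted p = 0.241). Of 8 tested neuroendocrine and secretory markers, Spink1 fell and none rose, and 1 fell when adjusted over the list alone. Reg3g was at 1949 ± 2580 and 391 ± 101 CPM (edgeR adjusted p = 0.414) and Chga at 812 ± 151 and 540 ± 408 CPM (0.720). Their median was -0.71, and the camera call (adjusted p = 0.00942) was lost with an estimated correlation (adjusted p = 0.213), with no low-count filter (0.0969) and without irradiated replicate 1 (camera adjusted p = 0.0520). None of 12 tested cortical epithelial markers passed over all genes or over the list alone. Ccl25, a chemokine for thymocyte progenitors, was at 174 ± 176 and 36.2 ± 20.2 CPM (edgeR adjusted p = 0.314), with exons that overlap an opposite-strand gene, and Tbata at 239.5 ± 265 and 74.5 ± 8.58 CPM (0.389). Their median was -0.65, and the camera call (adjusted p = 0.0138) was lost with an estimated correlation (adjusted p = 0.291) and without untreated replicate 4 (adjusted p = 0.0522). It was lost too with no low-count filter (camera adjusted p = 0.0987, median -0.33), without untreated replicates 1 and 2 (0.0832, median -0.14) and without untreated replicate 2 and irradiated replicate 4 (0.0762, median -0.32). Leaving out untreated replicate 1 gave a median of -0.37, and untreated replicate 2 of -0.41. Of 17 tested medullary epithelial markers, 1 rose and 0 fell. The tight junction gene Cldn4 rose from 159 ± 55.3 to 342 ± 52.6 CPM (1.11 ± 0.23, edgeR adjusted p = 0.0318), and was kept only without untreated replicate 2 or irradiated replicate 3 (up to 0.109). With adjustment over the list alone, 2 rose and 1 fell. The median was -0.44, and 0.04 without untreated replicate 2 (camera adjusted p = 0.658 over all libraries).

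Summed over each marker list, none of the 14 totals of other cell types passed the exact permutation test after adjustment. The smallest possible p was 0.00794, so a single total could not have passed on its own, and equal composition is not shown. At unadjusted p under 0.05 there were 5. The thymocyte and fibroblast totals are given above. Cortical epithelial markers totalled 1197 ± 565 and 673 ± 85.4 CPM, and microfold markers 2974 ± 1052 and 1649 ± 108 CPM (both exact permutation p = 0.0159, adjusted p = 0.0741). Neuroendocrine and secretory markers totalled 3118 ± 2633 and 1135 ± 457 CPM (exact permutation p = 0.0476, adjusted p = 0.133). Untreated replicate 2 was the highest library for the cortical (2194 CPM), medullary (12863 CPM), microfold (4517 CPM), neuroendocrine (7757 CPM), keratinised (3556 CPM) and ciliated and muscle (642 CPM) totals. The granulocyte and mast cell total was 371 ± 299 and 960 ± 1060 CPM, with irradiated replicate 1 at 2545 CPM (exact permutation p = 0.183, adjusted p = 0.347). Totals of B cell (231 ± 83.7 and 186 ± 36.1 CPM), innate lymphoid and NK cell (130 ± 89.4 and 58.3 ± 13.1 CPM), erythroid (285 ± 67.1 and 314 ± 39.6 CPM) and endothelial markers (3238 ± 1174 and 3776 ± 1873 CPM) had exact permutation p of 0.405, 0.151, 0.397 and 0.730. Those of keratinised (982 ± 1442 and 807 ± 391 CPM) and of ciliated and muscle mimetic markers (463 ± 123 and 453 ± 65.2 CPM) had exact permutation p of 0.571 and 0.984. For the keratinised total the tested mean log2 difference was 0.51, of the opposite sign to the difference of the mean CPM, since the other untreated libraries lay at 199.9 to 464 CPM. That difference was 1.19 without untreated replicate 2, 0.31 without untreated replicate 1, 0.23 without irradiated replicate 1 and 0.17 without untreated replicate 4.

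**Figure D3:**
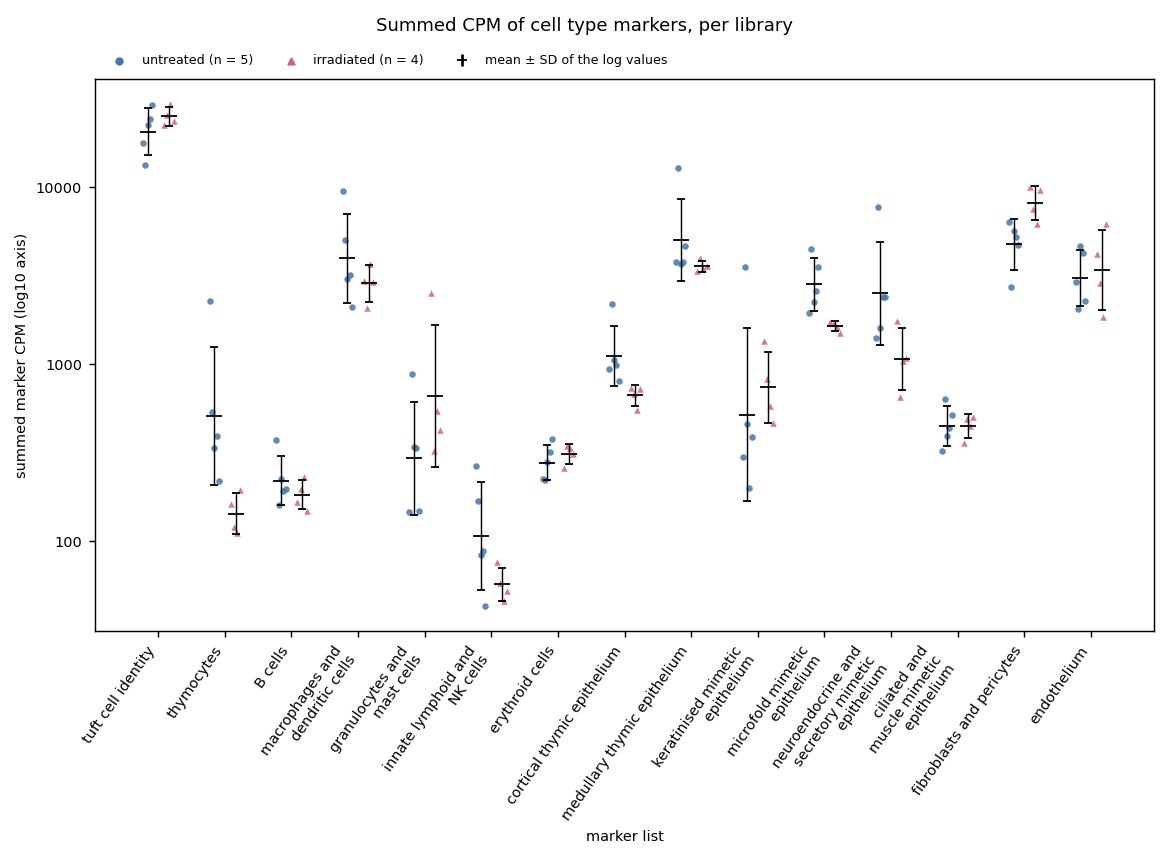
Summed CPM of each cell type's marker genes on a log10 axis, with the marker lists along the horizontal axis. Circles are the 5 untreated and triangles the 4 irradiated libraries, black bars are the mean ± SD of the log values, and no total of another cell type passed the exact permutation test after adjustment. With a smallest possible p of 0.00794, that test could not pass a single total on its own.

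The remaining lists did not pass by camera. None of the 20 tested DNA repair genes passed (median -0.26, camera adjusted p = 0.0811). Camera called that list down without untreated replicates 2, 3 or 5 or irradiated replicate 3 (adjusted p of 0.0356, 0.0420, 0.0336 and 0.0469), and its median was -0.16 without untreated replicate 4, -0.12 without irradiated replicate 2 and -0.14 without irradiated replicate 4. None passed of 23 apoptosis regulators over all genes (median -0.04, adjusted p = 0.625), of which 1 rose and 0 fell when adjusted over the list alone. Of 20 tested thymus growth and regeneration factors, Hbegf, a ligand of the epidermal growth factor receptor, rose from 47.8 ± 17.0 to 123 ± 46.4 CPM (log2 fold change 1.37 ± 0.29, edgeR adjusted p = 0.0339) and Fgf21 fell. The counts over that list alone were also 1 and 1, and its median was -0.04 (camera adjusted p = 0.625). Hbegf was the called gene whose groups overlapped, and it was kept only without untreated replicate 4 or irradiated replicate 4 (edgeR adjusted p of up to 0.156). None of 65 cytosolic ribosomal protein genes, 54 genes of oxidative phosphorylation or 18 genes of class I antigen presentation passed over all genes or over the list alone, with medians of -0.06, -0.08 and -0.04 and camera adjusted p of 0.505, 0.127 and 0.619. Oxidative phosphorylation was called down without irradiated replicate 3 (camera adjusted p = 0.0407), and its median was -0.05 without untreated replicate 1, -0.04 without untreated replicate 2 and -0.03 without irradiated replicate 4. Of 17 genes of glycolysis and hypoxia, none passed over all genes, and 1 rose and 2 fell when adjusted over the list alone (median 0.09, mean -0.02, camera adjusted p = 0.701). None of 9 keratinised mimetic markers (median -0.70 with the camera direction up, adjusted p = 0.701), 9 ciliated and muscle mimetic markers (median 0.17, adjusted p = 0.658) or 18 endothelial markers (median 0.14, adjusted p = 0.367) passed over all genes or over the list alone. The keratinised list was called up, with a median above 0, without untreated replicate 2 (camera adjusted p = 0.00420, median 0.56) and by limma-voom (0.0331, median 0.83). The endothelial list was called up without untreated replicate 3 (0.0482) or irradiated replicate 3 (0.00490). No mitochondrially encoded gene of the list fixed beforehand was among the listed genes. The lists of B cells (2 genes tested), granulocytes and mast cells (4), innate lymphoid and NK cells (1) and erythroid cells (2) were too short for camera, and none of their genes passed.

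By camera with its preset correlation, 14 of the 29 tested lists moved, 5 up and 9 down. With a correlation estimated for each list, 0 of the 29 passed and 6 were under an unadjusted p of 0.05. An exact permutation test of each list's mean, added after the data were seen, gave 0 lists past adjustment and 11 at an unadjusted p under 0.05, with a lowest adjusted p of 0.0628 and a smallest possible p of 0.00794, which limits what it can show for any single list. Of 100 splits of the 9 libraries into 5 and 4, 7 gave 14 or more lists, the real split included.

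**Figure D4:**
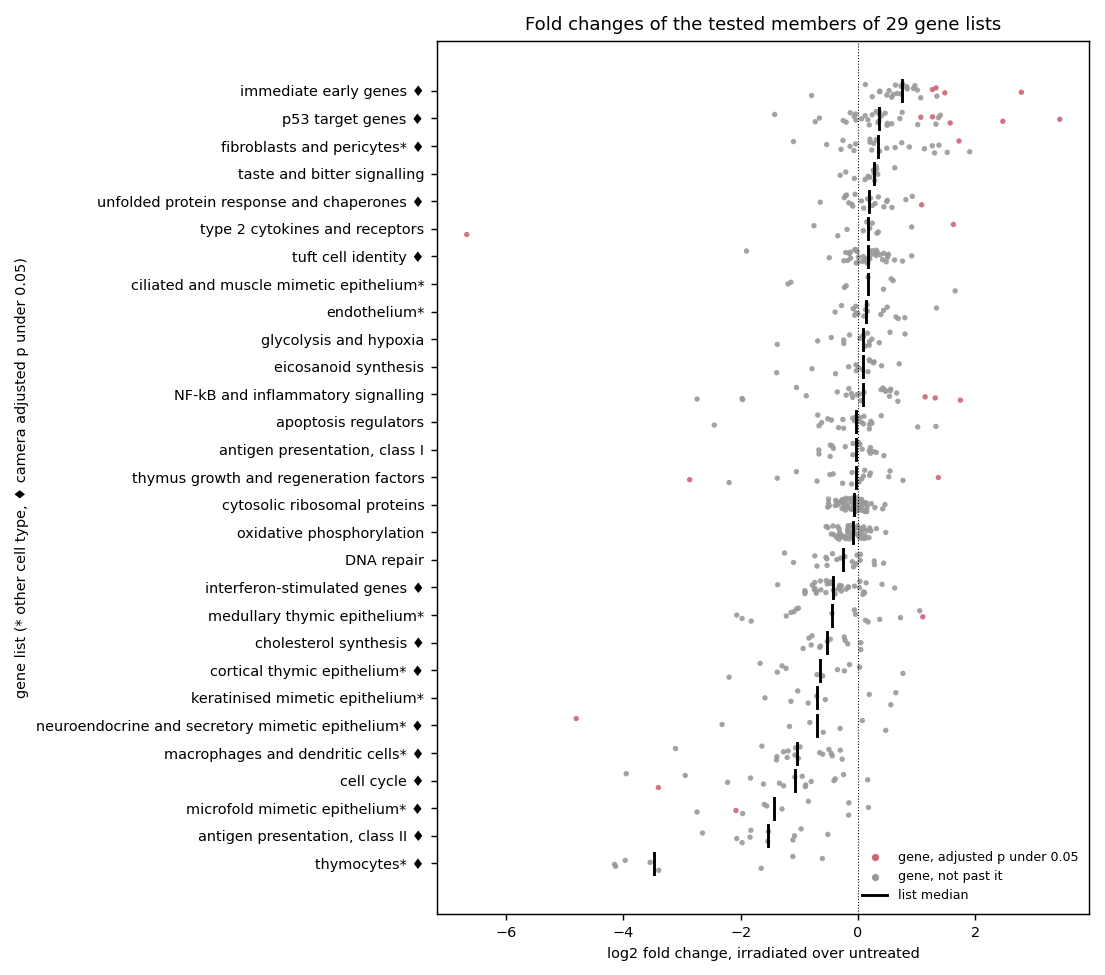
Fold changes of the tested members of 29 gene lists, with log2 fold change of irradiated over untreated on the horizontal axis and the lists on the vertical axis. Each dot is a gene, red where its edgeR adjusted p is under 0.05, vertical bars are list medians, and diamonds mark the 14 lists called by camera with its preset correlation, none of which was called with an estimated correlation.

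The authors' deposited table gave 242 genes as passing their own comparison, 147 higher and 95 lower after irradiation. All 242 had an absolute log2 fold change of at least 1, a limit not set for the edgeR calls here, and 289 genes had an adjusted p under 0.05 in the authors' table. Of the edgeR calls, 104 of the 109 higher and 11 of the 11 lower genes also passed in the authors' deposited table. Of the genes passing there, 9 higher and 36 lower ones were removed by the low-count filter used here, and 0 had the opposite direction in the edgeR fit.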

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

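The mesothelial marker list was drawn up after the rises were seen and before its own values were looked at, and the tests of leaving out untreated replicates 1 and 2 and of tissue handling were chosen after the results were seen. Of 220 groups of values checked, 11 held a library far from the others, and chance gives about 1 in 20, or 11. The value given is the gap to the nearest library over the whole range of the group, with a critical value of 0.71 for 5 libraries and a higher one for 4. Untreated replicate 2 stood apart in 7 of the 11. It was high for the cortical epithelial total (0.728; 2194 CPM against 806 to 1058), the medullary epithelial total (0.81; 12860 against 3697 to 4687), Tbata (0.798; 712.6 against 97.4 to 146) and Upk1b (0.733; 84.4 against 14.5 to 23.4). It was low for Flnc (0.833; 0 against 2.79 to 3.94), Il25 (0.744; 57.8 against 205 to 316) and Col3a1 (0.926; 38.5 against 177 to 200). Lck was high in untreated replicate 1 (0.754; 213.6 against 19.5 to 35.6). Rspo1 was high in irradiated replicate 1 (0.881; 103 against 61.0 to 64.9), and irradiated replicate 4 was high for Jund (0.936; 1989 against 735 to 784) and low for Ccl25 (0.917; 6.31 against 41.4 to 48.7).

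Several of the named rises, Upk3b, Lrrn4, Gpm6a and Rspo1, are genes associated with mesothelium, the lining of body cavities, as are Upk1b and Aldh1a2, picked out after their values were seen. With all libraries thinned to the smallest total, 12 of the 12 named rises stayed called. Thinning leaves the expected fold change of scaled counts nearly unchanged, so this says little about depth as a cause. Mean totals were close, at 772085 counts in untreated and 752124 in irradiated libraries. RNA of mesothelial cells in the irradiated libraries may be a source, and was tested on 12 other mesothelial markers, of which 7 were tested, 6 lay above 0 and 0 passed by edgeR. Their median log2 fold change was 0.227, at percentile 93.79 of 10000 random lists of matched expression (95th percentile 0.253), with Krt19 at 1404 ± 277 and 1789 ± 298 CPM and Msln at 436 ± 177 and 625 ± 203 CPM. The low-count filter kept Wt1, Bnc1, Tbx18 and Calb2 out of this test. Means in untreated and irradiated libraries were 7.63 and 44.1 CPM for Wt1, 2.36 and 7.03 CPM for Bnc1, and 2.47 and 6.02 CPM for Tbx18. Calb2 was lower in the irradiated libraries. The test leaves mesothelial RNA and a response of the sorted cells open. Tuft cells and other epithelium may also express markers such as Krt19 and hide a small share, and the gate is not stated.

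The thymocyte, cell cycle and class II lists had medians below 0 and were called down by camera, with 0 of 8, 1 of 17 and 0 of 11 genes passing by edgeR. All 3 calls were lost with an estimated correlation (camera adjusted p of 0.213, 0.305 and 0.291). Without untreated replicates 1 and 2, the thymocyte median was still -2.14, which argues against those libraries alone as its source, while the cell cycle median shrank from -1.08 to -0.435, as would follow if they carried most of it, and the class II median of -0.507 left this open. Within groups, cell cycle and thymocyte totals rose and fell together over the 9 libraries (r = 0.955, exact permutation p = 0.00208; r = 0.788, exact permutation p = 0.0556 without untreated replicates 1 and 2). The rank correlation was 0.8 (exact permutation p = 0.0177). Untreated replicate 1 was also highest for macrophage and dendritic cell (9498 CPM), B cell (375 CPM) and innate lymphoid (268 CPM) totals. Their relation to the cell cycle total was not tested. Cell cycle RNA may have come with thymocyte RNA, a hypothesis found and tested on the same libraries, but a link to thymocytes in particular is not shown. An effect of irradiation on thymocyte numbers, and so on RNA carried into the sort, was not tested, nor was RNA of macrophages and dendritic cells as a source of the class II transcripts.

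Of 26 immediate early genes 4 passed by edgeR, and the camera call of the list was lost with an estimated correlation (camera adjusted p = 0.199). The median of 0.75 is the same under both. With all libraries thinned to the smallest total the median was 0.751. Since thinning leaves the expected fold change of scaled counts nearly unchanged, this says little about depth as a cause. A different handling or dissociation time of the groups could also raise these genes. Of the tested members 96.2% lay above 0, as both irradiation and handling would give, and with no day or time in the labels these cannot be told apart.

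From all splits of the 9 libraries into 5 and 4, 100 were drawn. For genes higher after irradiation, 1 split gave as many as 109, the real one, with 1 gene as the highest of the others. For genes lower after irradiation it was also 1, with 11 genes against 3. Chance is thus unlikely to give either count, though 100 drawn splits cannot exclude it. For the 14 lists, 7 splits gave as many. The other splits gave a median of 8 lists and at most 18. The split with 18 set untreated replicates 1, 2, 4 and 5 against the rest, and so kept most of the real contrast. One that mixed the groups more, untreated replicates 1, 2 and 5 with irradiated replicate 1, gave 15. These splits are therefore not free of an irradiation difference, and chance is not excluded as a source of the number of lists.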

How the results depend on the processing

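The settings with replicates 1 to 4 unblocked, with untreated replicates 1 and 2 left out, with untreated replicate 2 and irradiated replicate 4 left out, and with permutation of list means were chosen after the data were seen. The 12 named rises, Cdkn1a, Eda2r, Fosb, Serping1, C3, C2, C1ra and Aldh1a2 kept their direction and call in all alternatives that tested them (21, and 20 for Eda2r), with adjusted p of at most 0.0368 for Gpm6a among the 12. The 109 higher genes were 184 by DESeq2, with all 109 shared, and 87 to 147 under the other settings that kept 9 libraries except thinning, with 84. The 11 lower genes were 100 by DESeq2 (11 shared), 24 by limma-voom (7 shared), 22 with the replicate block (6 shared), 7 when thinned (5 shared) and 17 without untreated replicate 2 and irradiated replicate 4 (5 shared). The cause of these differences was not tested. DESeq2 tested 13153 genes, thinning left 7596, and the last setting and the replicate block used fewer libraries. With no low-count filter edgeR tested 13223 genes and called 10 lower. This argues against the number of genes tested as the only reason for the 100 by DESeq2. Without the block, replicates 1 to 4 gave 75 higher and 10 lower, and with it 91 and 22. The block also ended the calls of Ccl2 (edgeR adjusted p = 0.0610), Gbp4 and Kif22 and of the unfolded protein list (camera adjusted p = 0.0524), all kept with replicates 1 to 4 unblocked, and those of Lyz1, Fgf21, Hbegf and C1s1, which replicates 1 to 4 unblocked also ended. The DNA repair list was called down with the block (camera adjusted p = 0.0204) and with replicates 1 to 4 unblocked (0.0336). Residuals of libraries with the same number correlated at -0.123 to 0.141, and 1 of 4 irradiated libraries correlated best with its own number. These values give little sign that the numbers pair the libraries, but so few pairs cannot settle it. Leaving out 1 library gave 50 to 114 higher genes, 2 to 12 lower genes and 12 to 16 lists. The 14 lists were 0 with an estimated correlation, which allows for the genes of a list moving together, and 0 by exact permutation of list means (6 and 11 at an unadjusted p under 0.05). No marker total passed under any alternative, but with so few libraries the exact test can hardly call a single total. The pseudocount alternative for normalized values was not run, since the table holds counts.

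Values that changed sign were all of results that did not pass in the analysis reported, except the tuft identity list, and the cause was not tested. With the new sign, camera called the keratinised list by limma-voom (adjusted p = 0.0331), without untreated replicates 1 and 2 (0.0202) and without untreated replicate 2 and irradiated replicate 4 (4.37e-05), and the ribosomal list without untreated replicates 1 and 2 (0.00270). The NF-kB list was called up in 9 of 22 alternatives, these 2 settings among them (camera adjusted p of 0.00400 and 0.00414). The values that changed sign were 0.0029 for the ciliated and muscle total with DESeq2 size factors, -0.0294 for Epcam with upper quartiles, and -0.30 for the type 2 and 0.0259 for the class I list with no filter. The stricter filter gave -0.0408 for the type 2 and -0.00901 for the ciliated and muscle list. By limma-voom these were Epcam (-0.10) and the thymus growth (0.0155), keratinised (0.83) and endothelial (-0.16) lists, and with replicates 1 to 4 unblocked the thymus growth list (0.01656). Permutation of means gave -0.10 for the type 2 and 0.12 for the keratinised list. Without untreated replicates 1 and 2 these were the tuft identity (-0.0333), class I (0.0585), thymus growth (0.0672), ribosomal (0.20), keratinised (0.44) and endothelial (-0.0424) lists, Avil (-0.10), Il17rb (-0.0328), Gnb3 (-0.0708), Alox5 (-0.16) and Epcam (-0.17), and the totals of macrophages and dendritic cells (0.0667), erythroid cells (-0.0506), ciliated and muscle cells (0.01129) and endothelium (-0.0546). Without untreated replicate 2 and irradiated replicate 4 these were the thymus growth (0.13), oxidative phosphorylation (0.0074), glycolysis (-0.0330), medullary (0.0761), keratinised (0.84) and endothelial (-0.23) lists, Dclk1 (0.0442), Gnb3 (-0.0211), Alox5 (-0.0430) and Epcam (-0.0829), and the ciliated and muscle (0.0661) and endothelial (-0.27) totals.

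Leaving out 1 library gave ranges across 0 for the apoptosis (-0.134 to 0.0198), ribosomal (-0.134 to 0.095), class I (-0.169 to 0.066), thymus growth (-0.151 to 0.0337), medullary (-1.04 to 0.0442), keratinised (-0.921 to 0.560), eicosanoid (-0.0083 to 0.118), ciliated and muscle (-0.176 to 0.285), glycolysis (-0.0086 to 0.191) and endothelial (-0.0985 to 0.311) lists. The same held for Epcam (-0.094 to 0.121), Dclk1 (-0.466 to 0.146) and the ciliated and muscle (-0.120 to 0.118) and endothelial (-0.124 to 0.467) totals. The smallest library held 509157 counts, where 3 counts are 6.31 CPM, so changes of genes near that level are poorly measured.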

Other observations

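The complement genes were singled out after their values were seen, with no list fixed beforehand, and neither an excess of such genes nor an explanation was tested. Of the 109 higher genes, 7 belong to the complement system, namely C4b and Serping1 of the report, C3, C2, Cfb, C1ra and C1s1. C3 was at 745 ± 217 and 2409.5 ± 995 CPM (log2 fold change 1.69 ± 0.29, edgeR adjusted p = 0.00727), C2 at 60.5 ± 11.4 and 185 ± 42.1 CPM (1.61 ± 0.20, 0.00104), C1ra at 39.6 ± 15.4 and 136 ± 28.6 CPM (1.76 ± 0.28, 0.00489), Cfb at 97.8 ± 50.5 and 361 ± 153 CPM (1.88 ± 0.39, 0.0463) and C1s1 at 115 ± 35.8 and 244 ± 56.5 CPM (1.09 ± 0.25, 0.0455). Other complement genes were tested and did not pass by edgeR, among them Cfd, Cfp, C1qa, C1qb, C1qc, Cd55 and Cd59a. Serping1 is also on the fibroblast list, whose marker total was 4950 ± 1369 and 8343 ± 1785 CPM (exact permutation p = 0.0238, adjusted p = 0.0833). Each of the 5 genes was higher in all 4 irradiated libraries than in all 5 untreated ones, as were 108 of the 109 higher genes. C3, C2 and C1ra stayed called in all 21 alternatives. Cfb was kept among the fits leaving out 1 library only without untreated replicates 1 or 2 (edgeR adjusted p of up to 0.137 in the others), and C1s1 only without untreated replicate 2 or irradiated replicate 4 (up to 0.193). Exons of C2 and Cfb overlap a same-strand gene and those of C2 and C1s1 an opposite-strand gene, so their levels are uncertain.

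Of the 12 held-out mesothelial markers 4 lay below the low-count filter. Wt1 was at 7.63 ± 3.94 CPM in untreated and 44.1 ± 24.8 CPM in irradiated libraries, Bnc1 at 2.36 ± 1.29 and 7.03 ± 2.83 CPM and Tbx18 at 2.47 ± 1.02 and 6.02 ± 6.34 CPM. Calb2 went the other way, with 26 counts in the untreated libraries, all of them in replicates 1 and 2, and 0 in the irradiated libraries, at least 6.58-fold lower against a floor of 3 counts over the group. Muc16 was not listed. Upk1b was at 32.9 ± 29.02 and 196 ± 79.9 CPM (edgeR adjusted p = 0.0350, kept among the fits leaving out 1 library only without untreated replicate 2 or irradiated replicate 3, up to 0.114 in the others), and Aldh1a2 at 11.8 ± 5.96 and 70.5 ± 28.0 CPM (edgeR adjusted p = 0.00406).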
